A study of Mus musculus with 2 samples.

How the data were processed

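The study measured gene expression with Affymetrix mouse arrays in 2 groups of teratomas, those formed by C57BL/6 (B6) embryonic stem cells and those formed by EiPS cells, an induced pluripotent stem cell line. Per the labels' protocols and the series' design text, cells were injected under the skin of male B6 mice, tumours were removed at week 6, RNA of 2 tumours was pooled for each array, and biotin-labelled cRNA was made from 5 µg of total RNA. There is 1 array per group. The groups were taken from the labels, and the list of 9 genes attributed to the study's paper comes from background knowledge of that study, not from the files.

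The deposited values are probe set intensity values on a linear scale, made with Affymetrix Expression Console and the MAS5 method per the submitters' processing notes. Versions and settings are not given in the sources used here, and neither detection calls nor scanner images were used here. From the values, each array had a 2% trimmed mean of 500.2, so the authors' scaling had set both arrays to the same level before deposit. No further scaling was applied for the main values. MAS5 subtracts mismatch signal, which makes low signals noisy, and its scaling gives relative amounts: a difference in total RNA per cell would not be seen.

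Probe sets were named through the platform's gene annotation, updated by Entrez identifier with a RefSeq gene table (assembly GRCm38.p6, used for names only). Of 22690 probe sets, 64 were controls, 20380 had 1 gene symbol, 691 several and 1555 none. Of the 20380, 20351 were matched by identifier and 29 kept the annotation's symbol. Genes were named only from probe sets with 1 symbol, and the gene's value was that of its probe set with the highest mean log2 signal, for 12393 genes.

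A floor on low signals was set at the 90th percentile of the signals of 68 probe sets for receptors held to be silent in these tissues, which gave 25.4. It left 79.3% of probe sets above the floor on the B6 ES array and 82.1% on the EiPS array. A gene under the floor on 1 array was set to the floor there, and its difference is a bound, written "at least". Genes under the floor on both arrays (1405) were not compared, which left 10988, of which 10231 were above it on both arrays. A difference is the log2 signal of the EiPS pool less that of the B6 ES pool. No test, p-value or standard error was computed, since neither group has a replicate. The precision is set by the 1 array per group. Measurement noise was gauged by the SD of log2 differences between probe sets of the same gene (0.40 over 3813 genes; 0.50 at signals under 100, 0.41 from 100 to 1000 and 0.29 above), which leaves out the variation between tumours, arrays and labelling.

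In all, 44 gene lists (tissues, immune cells, pathways and controls) were written before the data were examined. For each, the median log2 difference over measured members was given with its percentile among 10000 random lists of the same size, drawn from 10 bins of mean expression. These percentiles describe the 2 arrays and are no test between the groups. Of the 9 genes of the study's paper, 8 are also members of other lists.

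The genes named follow a rule written beforehand. They are the 12 with the largest difference in each direction among genes above the floor on both arrays whose probe sets above the floor on both have the same direction. To these were added, in each direction, the 6 brightest genes above the floor on 1 array only, with no other probe set above the floor going the other way. Unnamed clones would have been passed over in both steps, and none came up. All members of the study's list and of the sex-linked list that had a probe set of their own were named, and up to 4 members with the largest absolute difference in each other list, with the largest in the opposite direction where both directions reached 2-fold. Actb and Gapdh were to serve as controls, but Gapdh has no probe set with its symbol alone and is given from the array's control probe sets. Where probe sets of a named gene differ in sign, this is said.

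Alternatives chosen beforehand were floors at the 75th and 98th percentiles of the silent receptors, no floor, log2(signal + 64), quantile normalization, equal medians, loess scaling with a span of 0.4, the mean over a gene's probe sets, and leaving out probe sets shared by several transcripts. A floor of 100 was added after the data were seen. Each list median was taken over the genes above the floor in use on 1 array or more. A higher floor can thus leave fewer genes, and no floor takes in every gene with a probe set of its own. The procedure was tested on simulated data for the EiPS and B6 ES arrays, run on 12393 genes with 100 genes changed by each size. The changed genes were above the floor on both arrays, and the noise had the SD between probe sets (0.40) at every signal level. Variation between tumours, arrays and labelling was left out, so the shares that follow are no error rates for the real arrays. Of genes changed by 1.5 on the log2 scale, 87% were found at 2-fold and 8% at 4-fold. Of those changed by 3, 100% were found at 2-fold and 98% at 4-fold, and of unchanged genes 1.11% at 2-fold and 0 at 4-fold. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.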

Results

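Gene expression was measured in teratomas, tumours of mixed differentiated tissue that pluripotent stem cells form after transplantation. The first array held RNA from tumours of C57BL/6 (B6) embryonic stem (ES) cells, called the B6 ES pool here. The other held RNA from tumours of EiPS cells, an induced pluripotent stem cell line of the same strain, whose tumours the submitters describe as regressing (the EiPS pool). RNA of 2 tumours was pooled for each array, and tumours had been taken at week 6 from under the skin of male B6 mice. With 1 array per group, no difference given here has a replicate check, and none was tested: values compare these 2 pools, not the cell lines in general. The number of arrays limits the precision. The median signal over 22690 probe sets was 179 in the B6 ES pool and 196 in the EiPS pool, and the highest signals were 17914 and 20986.

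The comparison asks which genes distinguish regressing tumours of EiPS cells from tumours of ES cells when both grow in hosts of their own strain. In the EiPS pool, genes of the skin's cornified layer, intestine, liver and yolk sac, fat, pluripotency, inflammatory cytokines and MHC class II presentation had higher signals, with list medians from 0.87 to 1.39 on the log2 scale. Skeletal muscle, smooth muscle and neuronal genes had lower signals, with medians of -1.16, -1.05 and -0.77. Single genes differed far more. Zg16, a secretory granule protein of intestinal goblet cells, was 52.7-fold higher in the EiPS pool, from a low B6 ES signal of 45.2. Myh4, the myosin heavy chain of fast adult muscle fibres, was 21.8-fold lower. Those markers of T cells and cytotoxic effector cells that could be measured had medians close to those of random gene lists. Several others were under the signal floor on both arrays.

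Of 10988 measured genes, 639 were at least 2-fold higher and 334 at least 2-fold lower in the EiPS pool, and 91 were at least 4-fold higher and 39 at least 4-fold lower. The share of higher genes depended on the scaling of the arrays and on the floor. It was 65.7% at 2-fold and 70% at 4-fold with the deposited scaling. After quantile normalization it was 53.01% (484 higher, 429 lower) and 59.3% (70 higher, 48 lower). With the deposited scaling and a floor of 100 it was 55.6% at both. Genes above the signal floor on 1 array only leaned further, with 136 at least 2-fold higher and 32 at least 2-fold lower. Across the 17452 probe sets above the floor on both arrays, the log2 signals correlated with Pearson's r of 0.951, a value across probe sets, which are not independent replicates. Several of the higher list medians rest partly on genes near the floor: with a floor of 100 they were 0.68 for liver and yolk sac, 0.62 for inflammatory cytokines, 0.55 for fat and 0.19 for pluripotency. Those values are medians over the genes still above that floor on 1 array or more. Without replicate arrays, the nearest gauge of measurement noise was the spread between probe sets of 1 gene, with an SD of 0.40 on the log2 scale, which leaves out variation between tumours.

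**Figure D1:**
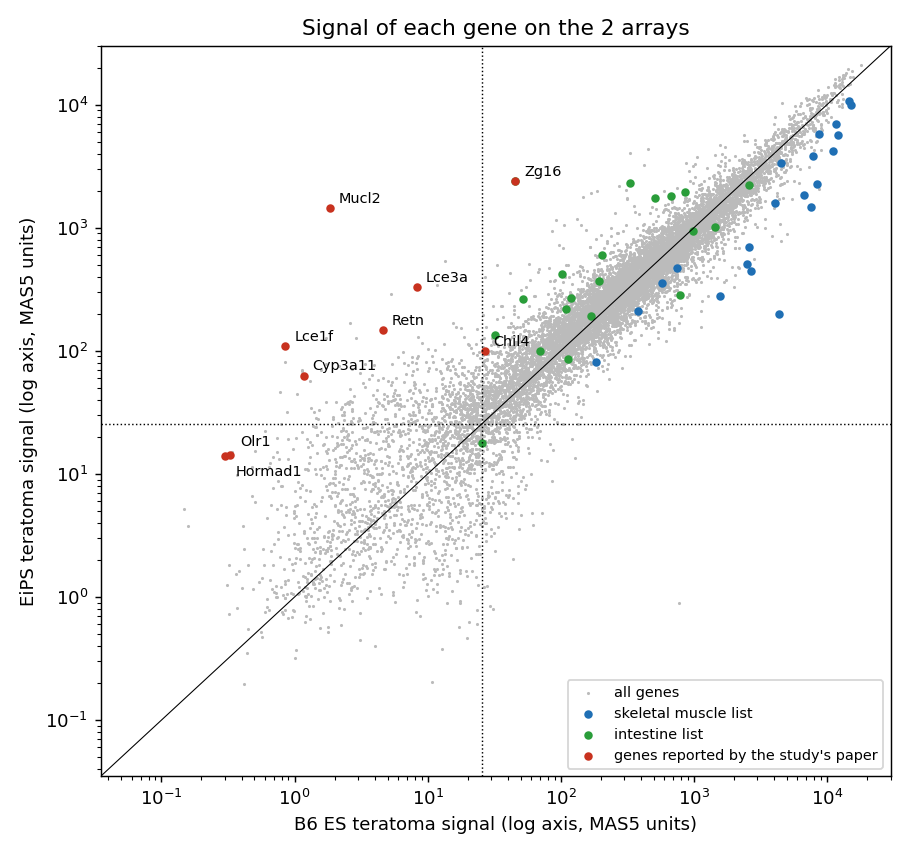
Signal of each gene in the B6 ES pool (x axis) and the EiPS pool (y axis), in MAS5 units on log axes; each point is 1 gene, and dotted lines mark the floor of 25.4. Skeletal muscle genes lie below the diagonal, and most intestine genes above it. Of the genes the study's paper reported, Zg16 (45.2 and 2381) lies farthest above it among those over the floor on both arrays, and Mucl2 (1.83 and 1439) among those under it in the B6 ES pool.

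The study's paper reported 9 genes for regressing EiPS tumours, and all 7 of those that could be compared were at least 2-fold higher in the EiPS pool, with a median log2 difference of 2.53. The study chose these genes on tumours of this kind, so their count is not independent evidence of a direction. Zg16 had the largest difference of all genes above the floor on both arrays, with signals of 45.2 and 2381, and its 3 probe sets differed by 4.72 to 5.91. Mucl2 (named Spt1 in the study), a mucin-like salivary protein, had a signal of 1.83 in the B6 ES pool, under the floor, and 1439 in the EiPS pool, at least 56.6-fold higher. The late cornified envelope genes Lce3a and Lce1f were at least 12.9-fold and at least 4.27-fold higher, and Retn, which encodes the fat-cell hormone resistin, at least 5.77-fold higher. Chil4 (Chi3l4 in the study), a chitinase-like protein, was 3.68-fold higher, and Cyp3a11, a liver cytochrome P450, at least 2.46-fold higher. Hormad1, a meiotic chromosome protein, and Olr1, a receptor for oxidised lipoprotein, were under the floor on both arrays. Hormad1 had signals of 0.298 and 13.9 and Olr1 of 0.325 and 14.2, so no fold is given for either. Because 5 of the 7 compared genes were above the floor in the EiPS pool only, their bounds depend on the floor. The list's median was 1.57 with the floor at the 98th percentile of silent receptors. With no floor it was 5.31, but over all 9 genes, Hormad1 and Olr1 included.

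**Figure D2:**
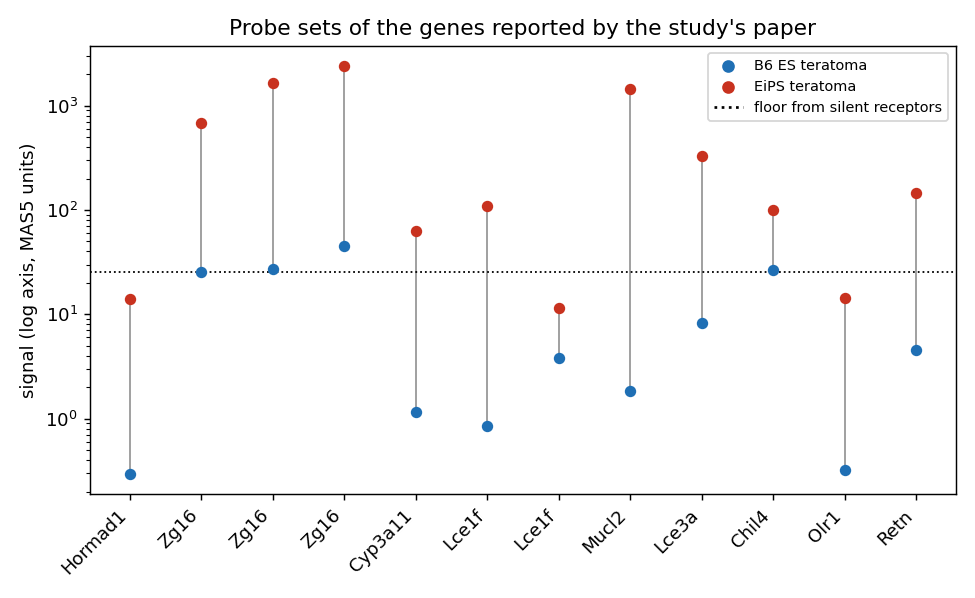
Signal of every probe set of the 9 genes the study's paper reported, in MAS5 units on a log axis, in the B6 ES pool (blue) and the EiPS pool (red); the dotted line is the floor of 25.4. Each probe set is brighter in the EiPS pool, but Hormad1, Olr1 and 1 probe set of Lce1f stay under the floor on both arrays.

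Apart from Zg16, Mt4 had the largest difference among genes above the floor on both arrays that were higher in the EiPS pool. Mt4, a metallothionein of stratified epithelium, was 15.0-fold higher. Trap1a, a tumour rejection antigen gene, was 14.7-fold and the imprinted gene Mest 12.6-fold higher. Lcn2, a neutrophil and epithelial defence protein, followed at 12.1-fold, the stomach genes Gkn1 and Gkn2 at 12.02-fold and 11.4-fold, and Igfbpl1 at 11.7-fold from a B6 ES signal of 25.5, just over the floor. Alb (albumin), Prap1, Pip and the pluripotency gene Dppa5a completed the 12 genes, at 10.99-fold, 10.6-fold, 10.4-fold and 9.96-fold. Trap1a, Mt4, Pip and Zg16 also had low B6 ES signals, of 27.2, 33.4, 41.3 and 45.2. These lie under the 98th percentile of the silent receptors (49.6). With the floor there, the folds of these genes and of Igfbpl1 would be smaller and only bounds. On the lower side, Myh4 was followed by Tmod4, a thin-filament protein of muscle (7.30-fold lower), the muscle glycogen phosphorylase Pygm (6.10-fold), myoglobin (Mb, 6.02-fold), Pgam2 (5.75-fold), the calcium pump Atp2a1 (5.66-fold) and the regulator Myf6 (5.62-fold). Scgb3a2, an airway secretoglobin, was 5.48-fold lower, and Trdn, Myh1, Ckmt2 and Myot, all muscle genes, were 5.39-fold, 5.21-fold, 5.12-fold and 5.06-fold lower. Of genes above the floor on 1 array only, Mucl2, Prol1 (at least 21.2-fold), Chil3 (at least 13.4-fold), Lce3a, Adipoq (at least 11.4-fold) and the testis cytochrome c gene Cyct (at least 6.601-fold) were the brightest in the EiPS pool. The brightest in the B6 ES pool were Prpmp5 (770 and 0.889, at least 30.3-fold lower in the EiPS pool), Tacr3 (at least 5.31-fold), Rasal1 (at least 5.00-fold), Klk1b21 (at least 4.78-fold), Sowaha (at least 4.06-fold) and Itgb7 (at least 3.44-fold).

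Skeletal and smooth muscle genes were lower in the EiPS pool as groups, and cardiac genes had a lower median with members going both ways. All 21 measured members of the skeletal muscle list were lower, 13 of them by at least 2-fold, and the median of -1.16 lay below those of all 10000 random lists of matched expression. Myh4 had signals of 4324 and 198, Mb of 2698 and 448, and Myf6 of 1565 and 279. In the smooth muscle list, 11 of 12 members were lower and 6 by at least 2-fold (median -1.05, below all random lists): the contractile genes Cnn1, Smtn and Actg2 were 4.25-fold, 2.51-fold and 2.48-fold lower, and Myh11 3.79-fold. The cardiac list had a median of -0.48, also below all random lists, with 3 of 16 members at least 2-fold lower, namely Nppa (at least 2.45-fold), Myh6 (2.40-fold) and Tnnt2 (2.11-fold), and Myl2 at 1.82-fold lower; 11 members were lower and 5 higher, of which Tnni3, at 0.65, differed most (named after its value was seen). With log2(signal + 64) the cardiac median was -0.30.

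Neuronal genes were lower in the EiPS pool, while lists of neural progenitors and glia were divided. In the neuron list, 17 of 19 members were lower, 6 by at least 2-fold, with a median of -0.77, below all random lists. Slc17a6, a glutamate transporter, was 4.48-fold lower, Th (tyrosine hydroxylase) 3.56-fold, the neurofilament gene Nefl 2.77-fold and Stmn2 2.66-fold. Among neural progenitor genes, Hes5 and Olig2 were 4.31-fold and 2.89-fold lower, whereas Neurog2 (at least 2.96-fold) and Otx2 (2.46-fold) were higher, with a list median of 0.16. The astrocyte and oligodendrocyte median was 0.09, and -0.09 after quantile normalization and -0.03 after loess scaling. Within it, Mobp, a myelin protein gene, was 7.58-fold higher by its brightest probe set, but its 3 probe sets ranged from 0.43 to 2.92; Gfap was 1.91-fold higher, and Olig1 and Sox10 were 2.62-fold and 2.36-fold lower. Of 6 measured genes of retina, lens and pigment cells, Rlbp1 and Cryab were 2.93-fold and 2.07-fold lower, Dct at least 2.05-fold higher and Crx at least 1.32-fold higher. That list's median of 0.19 turned to -0.07 after quantile normalization, and was also below 0 with higher floors, which left fewer genes.

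Genes of the epidermis and of several gut-derived tissues were higher in the EiPS pool. All 18 measured genes of the cornified envelope and late epidermis list were higher, 13 by at least 2-fold, with a median of 1.39, above all random lists; without Lce3a and Lce1f, which the study had picked, the median was 1.19 and 11 of 16 were at least 2-fold higher. The full list's median was 0.76 with log2(signal + 64). Asprv1, a protease of the upper epidermis, and Lor (loricrin) were 4.21-fold and 4.18-fold higher. The keratinocyte list had a median of 0.37 (percentile 99.0 among random lists), with Krtdap 4.23-fold, Dsp 2.15-fold and Krt16 at least 1.92-fold higher. Hair follicle genes had a median of 0.25 (percentile 53.9) and no member at 2-fold: Tchh came closest at 0.997 on the log2 scale, Msx2 was 1.51-fold, Dlx3 1.27-fold and Padi3 at least 1.23-fold higher.

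In the intestine list, 11 of 20 genes were at least 2-fold higher in the EiPS pool and 1 at least 2-fold lower, 14 were higher and 6 lower by any amount, and the median was 1.08, above all random lists, and of 1.01 over the 19 genes other than Zg16. The goblet cell gene Tff3 was 6.95-fold, Krt20 5.13-fold and Clca1 4.202-fold higher, and the enterocyte fatty acid carrier Fabp2 was 2.73-fold lower. Liver and yolk sac genes had a median of 1.14, above all random lists, with 12 of 21 at least 2-fold higher, none lower by that much and 3 lower by less. Alb had signals of 86.1 and 946, Serpina1b and Ahsg were at least 5.11-fold and at least 4.50-fold higher, and Afp was 3.58-fold higher, with probe sets from 0.19 to 1.85. With 6 of the 21 genes above the floor on 1 array only, the liver and yolk sac median was 0.77 with the floor at the 98th percentile of silent receptors and 0.68 with a floor of 100. Stomach, lung and airway genes went both ways, 9 at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.10, which was 0.45 with a floor of 100 and 0.60 with none. The surfactant gene Sftpc was 6.57-fold higher, opposite to Scgb3a2. The exocrine pancreas and salivary gland list had a median of -0.22 although 4 of its 12 genes, Mucl2, Prol1, Pip and Cela1 (2.22-fold), were at least 2-fold higher; the median turned to 0.63 with no floor and 2.11 with a floor of 100. Endocrine genes had a median of -0.01 (-0.32 after quantile normalization, -0.57 with a floor of 100 and 0.0472 with probe sets averaged), with Sst (2.36-fold), Pcsk1 (at least 2.20-fold) and Chga (1.59-fold) lower and Ins2 at least 2.37-fold higher. In the list of mammary and other glands, with a median of 0.34, Krt7, Krt8 and Krt18 were 1.81-fold, 1.47-fold and 1.36-fold higher and Wfdc18 was lower by just under 2-fold (1955 and 980).

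Fat, fibroblast, endothelial and erythroid genes had higher medians in the EiPS pool. The adipocyte list had a median of 0.87 (percentile 99.99), with 9 of 11 genes higher and 4 at least 2-fold higher: Adipoq (5.27 and 291), Fabp4 (7.90-fold by its brightest probe set, and by 2.71 on the log2 scale by the other one above the floor on both arrays), Retn and Lpl (2.01-fold). Its median was 0.57 after quantile normalization and 0.40 with the floor at the 98th percentile of silent receptors. Fibroblast and matrix genes had a median of 0.34 (percentile 99.99), with Fn1 (fibronectin) 2.05-fold, Lum 1.91-fold, Pdgfrb 1.86-fold and Fap 1.71-fold higher. The cartilage and bone median was 0.25, turned to -0.02 after quantile normalization and was 0.77 with a floor of 100; Col2a1 and Col9a1, cartilage collagens, were 2.97-fold and 2.32-fold higher, Comp at least 2.14-fold higher, and Hapln1 2.28-fold lower by its brightest probe set, while another differed by -0.02. Endothelial genes had a median of 0.34 (percentile 97.8; 0.52 without shared probe sets), with Vwf, Robo4 and Flt1 2.01-fold, 1.88-fold and 1.74-fold higher and the tight junction gene Cldn5 1.85-fold lower. Of 7 erythroid genes (median 0.60, percentile 91.4), 5 were above the floor on 1 array only: Alas2, the first enzyme of haem synthesis in red cells, was at least 4.15-fold, Hba-x at least 1.60-fold, Hbb-y at least 1.52-fold and Hbb-b2 1.51-fold higher.

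**Figure D3:**
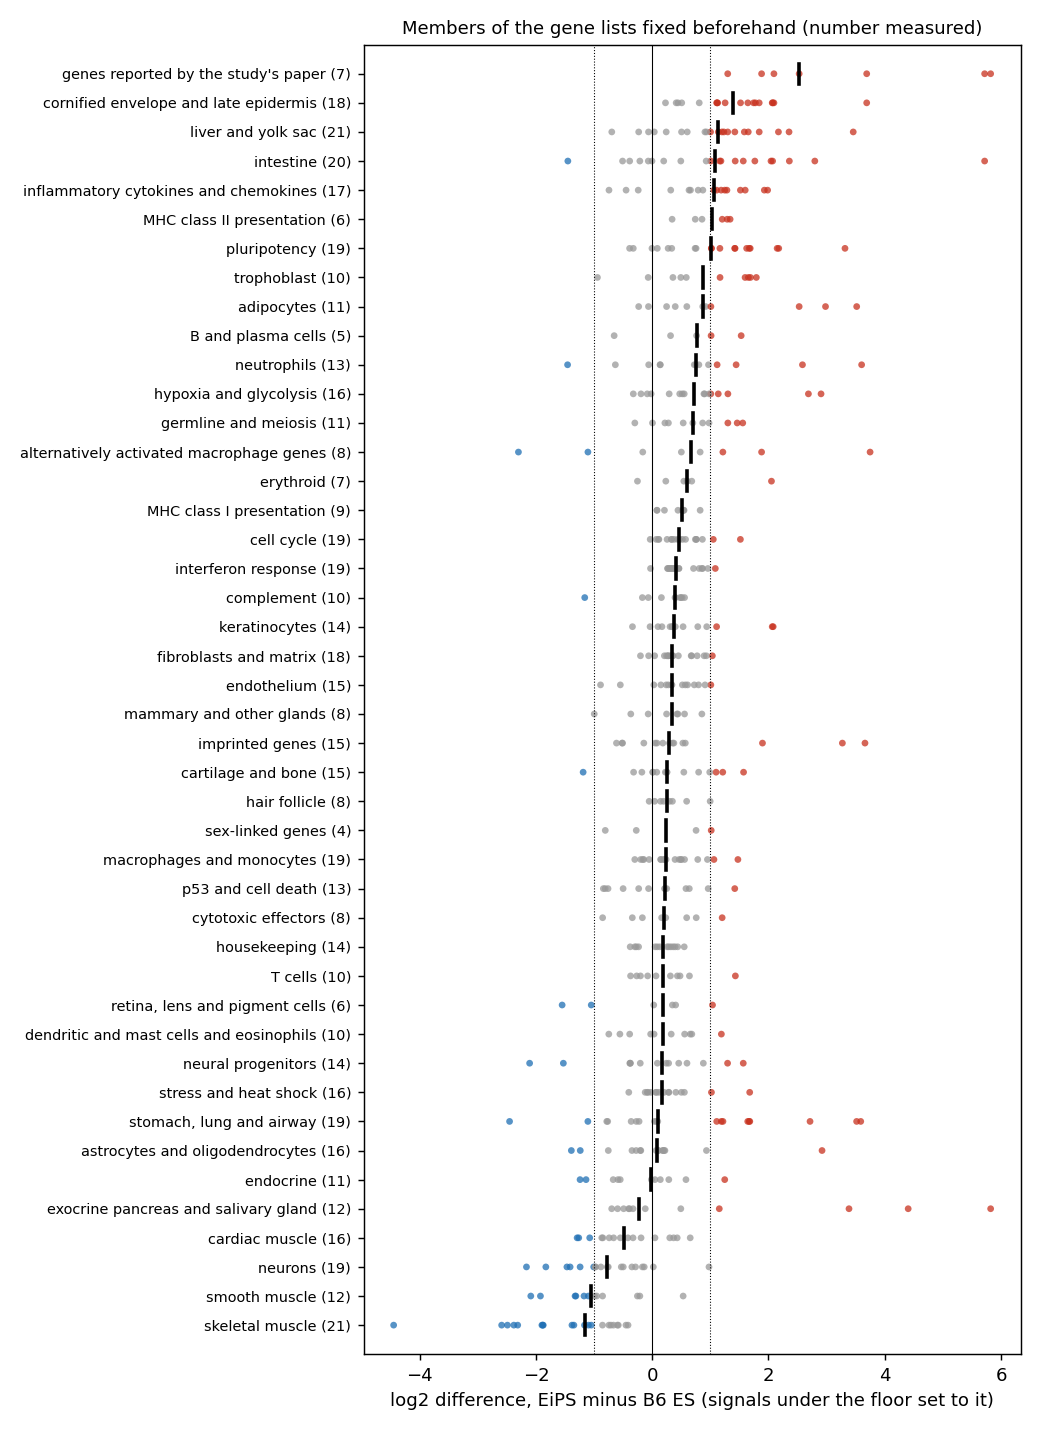
Log2 difference (EiPS minus B6 ES, x axis) of each measured member of the 44 gene lists, with the list's median as a black bar and the number measured in brackets; red and blue points are at least 2-fold higher or lower, and signals under the floor were set to it. The skeletal muscle list has the lowest median (-1.16) and, after the genes the study's paper reported, the cornified envelope list the highest (1.39); both keep their sign under every scaling of the arrays tried.

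T cell and cytotoxic effector lists had medians within those of random lists, while B and plasma cell genes and genes of inflammation and antigen presentation had higher medians in the EiPS pool. The T cell median was 0.19 (percentile 52.8) and the cytotoxic effector median 0.20 (percentile 46.2), and quantile normalization turned them to -0.08 and -0.04. With no floor the cytotoxic median was 0.49, over all 14 genes with a probe set of their own. Only 10 of 17 such T cell genes and 8 of 14 such cytotoxic genes were measured in the main values. Cd3d, Cd4, Cd8b1, Cd2, Lat, Foxp3 and Ctla4 were under the floor on both arrays. So were Gzmb, Gzmk, Fasl, Ifng, Ncr1 and Cst7 (all 13 named after their values were seen). The medians therefore do not cover these genes. In the T cell list only Il7r reached 2-fold (2.70-fold higher); Cd8a was at least 1.56-fold and Cd5 1.35-fold higher, and of the probe sets of Cd28, each above the floor on 1 array only, 1 was higher by at least 0.48 and the other lower by at least 0.35 on the log2 scale. Signals of these markers were low, at most 81.7 for Il7r, Cd8a, Cd5 and Cd28. Gzma (granzyme A) was 2.30-fold and Nkg7 1.69-fold higher, Klrd1 at least 1.51-fold higher and Klrk1 at least 1.81-fold lower. B and plasma cell genes had a median of 0.76 (percentile 97.0) over 5 measured genes, of 10 with a probe set of their own. Ighm was 2.89-fold higher by its brightest probe set, but its 5 probe sets above the floor ranged from 0.25 to 1.53. Sdc1 was 2.02-fold and Jchain 1.70-fold higher, and Blk 1.57-fold lower. Cd79b differed by only 0.32 on the log2 scale. Ms4a1, Cd79a, Pax5, Cr2 and Pou2af1 were under the floor on both arrays (these and Cd79b named after their values were seen). The list's median was 0.26 after quantile normalization.

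Inflammatory cytokine and chemokine genes had a median of 1.06, above all random lists, with 14 of 17 higher in the EiPS pool and 9 at least 2-fold: the neutrophil attractant Cxcl1 was 3.96-fold, and the monocyte attractants Ccl7, Ccl2 and Ccl8 were 3.81-fold, 3.03-fold and 2.86-fold higher. The median was 0.62 with a floor of 100, since several of these genes had low signals. MHC class II genes were all higher, with a median of 1.03, above all random lists: H2-Ab1 was 2.53-fold, the invariant chain gene Cd74 2.44-fold, H2-Eb1 2.30-fold and H2-Aa 1.81-fold higher. MHC class I presentation genes had a median of 0.52 (percentile 99.8) and none at 2-fold, with Psmb8 at 1.77-fold, Psmb9 at 1.46-fold, Tap2 at 1.45-fold and H2-K1 at 1.45-fold higher. In the interferon response list 18 of 19 genes were higher, with a median of 0.41 (percentile 99.1): Cxcl10 was 2.12-fold, Rsad2 1.94-fold, Mx2 1.82-fold and Irf7 1.81-fold higher. Complement genes had a median of 0.40 (percentile 97.3), with 7 higher and 3 lower: C1qb, C1ra and C1qc were 1.47-fold, 1.43-fold and 1.41-fold higher and C2 2.24-fold lower.

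Of the myeloid lists, those of neutrophils, macrophages and alternatively activated macrophages had medians above most random lists, and that of dendritic cells, mast cells and eosinophils did not. Neutrophil genes had a median of 0.75 (percentile 99.9), with 10 higher and 3 lower. Besides Lcn2, S100a9 was 6.00-fold and Ltf 2.72-fold higher, and Cd177 was 2.74-fold lower. Lcn2 and Ltf are also among the secreted defence proteins of epithelia described below. The other lower members were Elane (-0.63) and Csf3r (-0.06). Mpo differed by 0.14, Mmp8 by at least 0.13, and Cxcr2 was under the floor on both arrays (these 5 named after their values were seen). The list's median was 0.49 with log2(signal + 64) and 1.21 with a floor of 100. The macrophage and monocyte median was 0.24 (percentile 95.05), with 14 of 19 genes higher and 5 lower, namely Itgam (-0.30), Cd14 (-0.20), Mrc1 (-0.16), Csf1r (-0.14) and Adgre1 (-0.0532), named after their values were seen. Of the others, Cd68 was 2.09-fold, Lyz2 1.93-fold and Lyz1 1.72-fold higher, and Msr1, a scavenger receptor, 2.78-fold higher by its brightest probe set; other probe sets of Lyz1 and Msr1 had the opposite sign (-0.04 and -0.28). Genes of alternatively activated macrophages went both ways around a median of 0.66 (percentile 98.3): the chitinase-like Chil3 and Chil4 and Arg1 (2.32-fold) were higher, and Retnla was 4.93-fold lower. That median was 0.17 with no floor. Dendritic cell, mast cell and eosinophil genes had a median of 0.18 (percentile 47.2), with Itgax 2.28-fold, Kit 1.60-fold and Flt3 1.57-fold higher and Cd209a at least 1.68-fold lower. This median changed with the floor, but over different genes. With the floor at the 98th percentile of silent receptors or at 100, only Itgax, Kit and Zbtb46 (-0.39, named after its value was seen) were left. It was then 0.68, the value of Kit. With no floor it was 0.84, over all members with a probe set of their own.

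The hypoxia and glycolysis list had a median of 0.72, above all random lists, with 12 of 16 genes higher in the EiPS pool and 5 at least 2-fold. Its 4 lower members were all glycolytic genes, named after their values were seen: Aldoa (-0.33), Tpi1 (-0.19), Ldha (-0.0857) and Hk2 (-0.0188). Car9, a carbonic anhydrase induced by low oxygen, was 7.49-fold, the vasodilator peptide gene Adm 6.44-fold, Vegfa 2.47-fold and Egln3 2.20-fold higher. Cell cycle genes had a median of 0.46 (percentile 99.9), with 18 of 19 higher: Tyms at least 2.86-fold, Bub1 2.07-fold, Kif11 1.82-fold (by its other probe set above the floor on both arrays -0.08 on the log2 scale) and Cdc20 1.69-fold. Stress and heat shock genes had a median of 0.16 (percentile 93.7), with the haem oxygenase Hmox1 3.20-fold, Hspa1b 2.03-fold, Hspa1a 1.47-fold and Fos 1.42-fold higher. The p53 and cell death median was 0.21 (percentile 87.7), and -0.05 when probe sets were averaged; the death receptor gene Fas and Bcl2l11 were 2.68-fold and 1.95-fold higher, and Gadd45a and Pmaip1 were 1.79-fold and 1.75-fold lower.

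Most pluripotency genes were higher in the EiPS pool, many of them from signals under the floor in the B6 ES pool. The list's median was 1.02, above all random lists, with 16 of 19 genes higher and 11 at least 2-fold higher. Dppa5a had signals of 106 and 1052, Tdgf1 and Dppa4 were at least 4.52-fold and at least 4.44-fold higher, and Pou5f1 (0.852 and 81.8) at least 3.22-fold higher. Because 9 of the 19 were above the floor on 1 array only, the median was 0.37 with the floor at the 98th percentile of silent receptors. With a floor of 100 it was 0.19, but over fewer genes. That floor left out Pou5f1, Nanog, Utf1 and Gdf3, among others, as under it on both arrays. It kept Sox2, Klf4, Myc, Klf2, Tbx3, Tdgf1, Dppa4 and Dppa5a (genes not named before were named after their values were seen). Germline and meiosis genes had a median of 0.70 (percentile 97.8), with Ddx4 and Sycp3 at least 2.94-fold and at least 2.75-fold, Dmc1 2.46-fold and Stra8 1.97-fold higher, with signals of at most 78.7. In the trophoblast list, with a median of 0.88 (percentile 99.4), the homeobox genes Rhox9, Rhox5 and Rhox6 were 3.46-fold, 3.23-fold and 3.15-fold and Tpbpa 3.03-fold higher. The trophoblast and germline medians were 0.39 and 0.28 with a floor of 100, and 0.44 for both with log2(signal + 64). The germline value with a floor of 100 is that of Rec8 alone (named after its value was seen).

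The imprinted genes had a median of 0.30 (percentile 99.2) but 3 members with large differences. Mest was 12.6-fold, the maternally expressed long noncoding RNA gene Meg3 9.66-fold and its neighbour in the same imprinted cluster, Rian, 3.72-fold higher in the EiPS pool, while Igf2r was 1.53-fold lower. All 5 probe sets of Meg3 were higher (2.54 to 3.95), as were all 3 of Rian (1.90, 1.95 and at least 1.32). The list's median was 0.10 after quantile normalization and 0.13 with log2(signal + 64). Sex-linked genes showed no common direction. Xist, the X-inactivation RNA, was 2.02-fold higher at signals of 50.9 and 103 by 1 of its 3 probe sets. That probe set is of the kind shared by several transcripts, and the others were under the floor on both arrays. Whether Xist itself was expressed or differed therefore stays open. Of the Y-linked genes, Kdm5d was 1.69-fold higher, Eif2s3y 1.75-fold lower and Uty 1.21-fold lower with probe sets of opposite sign. Usp9y and Zfy2 were under the floor on both arrays. The sex-linked median of 0.24 was -0.19 with no floor.

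Reference genes and controls were close to equal, with exceptions. Housekeeping genes had a median of 0.19 (percentile 95.7; 0.0388 after quantile normalization), with Pgk1, Rpl13a and Rps18 1.46-fold, 1.35-fold and 1.31-fold higher and Hprt 1.30-fold lower. Actb was 1.09-fold higher, and lower after quantile normalization (-0.10 on the log2 scale). The array's control probe sets for beta-actin and Gapdh had medians of 0.01 and -0.05, and the ratios of their 3' to 5' probe sets, a sign of RNA integrity, were 1.35 and 1.49 for beta-actin and 0.829 and 0.798 for Gapdh in the B6 ES and EiPS pools. All 3 control probe sets for 18S ribosomal RNA were lower in the EiPS pool, with a median of -1.98. The 18 hybridisation controls were all higher (median 0.28), and 22 of the 24 poly-A spike controls lower (median -0.32, from -1.17 to 0.10). The 5' probe sets of DapX and ThrX fell more than the 3' ones (-1.17 against -0.56, and -0.83 against -0.48), and those of PheX were alike (-0.17 and -0.16). These median shifts were smaller than the medians of the cornified envelope, intestine, skeletal muscle and smooth muscle lists, except for that of 18S RNA, which was larger. But the lowest poly-A control, at -1.17, was as far from equal as the skeletal muscle (-1.16), intestine (1.08) and smooth muscle (-1.05) medians. The median hybridisation and poly-A shifts were larger than the macrophage median (0.24). They were close to those of fibroblasts (0.34), endothelium (0.34), keratinocytes (0.37), complement (0.40) and the interferon response (0.41).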

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

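The floor of 100 was chosen after the data were seen, and the other alternatives beforehand. The signs of 35 of 44 list medians and of 191 of 192 named genes were the same under every alternative in which they could be measured; the exception among genes was Actb after quantile normalization (-0.10). Under all alternatives, 13 of the 44 list medians moved by less than the SD of medians of random lists, and 95 of the 192 named genes by less than the spread between probe sets. No alternative scaling moved a count of genes at 2-fold or 4-fold by over 1.5 times. No paired analysis was possible because each group has 1 array, and for that reason no array could be left out and no other split of the samples made. Signals near background are a limit: 757 of the measured genes were above the floor on 1 array only, and list medians that rest on them move with the floor. Unless a sentence says otherwise, the cause of a shift was not tested.

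Counts of genes moved most without a floor, to 443 higher and 224 lower at 4-fold and 1234 and 713 at 2-fold, where the spread between probe sets was 0.782, and with log2(signal + 64), which shrinks low signals by construction, to 32 and 20 at 4-fold and 246 and 187 at 2-fold. With a floor of 100, 40 genes were higher and 32 lower at 4-fold, and 305 higher and 244 lower at 2-fold.

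A floor of 100 left few genes in some lists: only Zap70 and Thy1 for T cells, Ighm and Sdc1 for B cells, and Rec8 for germline. Its dendritic and retina medians are the values of Kit and Cryab. With a floor of 100, list medians were 1.71 for the study's genes, -0.23 for T cells, 1.27 for B cells, 0.33 for alternative macrophages, 1.21 for neutrophils, 0.68 for dendritic and mast cells, 0.62 for cytokines, 0.19 for pluripotency, 0.28 for germline, -0.53 for neurons and -0.0646 for astrocytes. Further medians were -1.05 for retina, 1.71 for cornified envelope, -0.30 for cardiac muscle, 0.77 for cartilage and bone, 0.55 for adipocytes, 0.45 for stomach and lung, 0.68 for liver, 2.11 for exocrine glands, -0.57 for endocrine, 0.39 for trophoblast and -0.0799 for sex-linked genes. With no floor they were 5.31 for the study's genes, 0.49 for cytotoxic effectors, 0.17 for alternative macrophages, 0.96 for neutrophils, 0.84 for dendritic and mast cells, 0.87 for cytokines and 1.43 for pluripotency. Further medians were 1.84 for cornified envelope, 0.60 for stomach and lung, 0.63 for exocrine glands, -0.55 for endocrine, 0.59 for trophoblast and -0.19 for sex-linked genes. With log2(signal + 64) they were 1.62 for the study's genes, 0.39 for B cells, 0.39 for alternative macrophages, 0.49 for neutrophils, 0.56 for cytokines, 0.59 for pluripotency, 0.44 for germline and 0.76 for cornified envelope. Further medians were -0.30 for cardiac muscle, -0.77 for smooth muscle, 0.53 for adipocytes, 0.80 for intestine, 0.85 for liver, 0.44 for trophoblast and 0.13 for imprinted genes. The floor at the 75th percentile of silent receptors gave 2.90 for the study's genes, 0.32 for B cells, 0.94 for neutrophils, 0.87 for cytokines and 1.39 for pluripotency, and that at the 98th percentile 1.57 for the study's genes, 1.04 for neutrophils, 0.68 for dendritic and mast cells, 0.37 for pluripotency, -0.49 for retina, 1.04 for cornified envelope, 0.40 for adipocytes, 0.77 for liver and 0.82 for exocrine glands.

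Quantile normalization gave -0.0787 for T cells, 0.26 for B cells, 0.52 for neutrophils, 0.81 for cytokines, 0.0695 for p53, 0.80 for pluripotency, -0.0873 for astrocytes, -0.0737 for retina and -1.31 for skeletal muscle. Further medians were -0.0227 for cartilage and bone, 0.57 for adipocytes, 0.95 for intestine, 0.98 for liver, -0.32 for endocrine, 0.63 for trophoblast, 0.10 for imprinted genes and 0.0388 for housekeeping. It also turned the median of cytotoxic effectors to -0.04. Loess scaling gave 0.41 for B cells and -1.28 for skeletal muscle, and equal medians 1.001 for liver. The mean over probe sets gave 0.79 for cytokines, -0.0472 for p53, 0.998 for liver and 0.0677 for housekeeping, and leaving out shared probe sets 0.87 for hypoxia, 1.65 for cornified envelope, 0.52 for endothelium, -0.29 for endocrine and -0.27 for sex-linked genes. Among the values given here, medians with a sign opposite to the main value are those of exocrine glands, p53, cartilage and bone, T cells, cytotoxic effectors, astrocytes (also -0.0268 with loess scaling), retina and sex-linked genes; the endocrine median turned to 0.0472 with the mean over probe sets.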

Other observations

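Every gene group that the report does not describe was put together after its values were seen, so its count shows no direction of its own, and every test here was chosen after the result was seen except the count of ratios near background for Hormad1 and Olr1. Genes of lipid-handling macrophages were higher in the EiPS pool in all 8 members looked at (median 1.58): the glycoprotein Gpnmb was 7.46-fold, Clec4d 6.55-fold and the elastase Mmp12 6.24-fold higher. Secreted defence proteins of epithelia were higher in all 8 (median 1.90), among them the protease inhibitor Slpi (8.76-fold), the antibody transporter Pigr (5.50-fold), Muc3 (3.88-fold) and Dmbt1 (3.59-fold). Genes of vessel growth and matrix were higher in all 8 (median 1.89), with the endothelial gene Esm1 at 8.95-fold, Angpt2 at 4.55-fold, Ccn1 at 4.21-fold and the collagen-modifying enzyme Plod2 at 3.51-fold.

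Genes of muscle energy metabolism were lower in all 7 members looked at (median -2.36), including Pygm, Pgam2, Ckmt2, the enolase Eno3 (4.26-fold lower) and the insulin-responsive glucose transporter Slc2a4 (3.77-fold lower). A set of X-linked genes with expression restricted mainly to germline and placenta was higher in all 5 (median 1.79): Trap1a 14.7-fold, Fmr1nb at least 2.72 on the log2 scale, and Rhox9, Rhox5 and Rhox6. Probe sets without a gene name differed mainly in 1 direction. Of 995 measured probe sets with no gene symbol, 40 were at least 4-fold higher in the EiPS pool and 0 lower, and of 562 with several symbols 18 were higher and 0 lower, against 164 higher and 47 lower of 17560 with 1 symbol.

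For Hormad1 and Olr1, 2 of the genes the study's paper reported, whose signals all lie under the floor, noise near background cannot be told apart from expression, and 32.4% of signals from silent receptors exceeded that of Hormad1 in the EiPS pool. Of 2820 probe sets under the floor on both arrays, 3 others differed as much in the same direction and 1 in the opposite direction. Among the 68 silent receptor probe sets, the largest ratio of deposited signals was 15.6, against 46.8 for Hormad1 and 43.8 for Olr1. But the study had picked these 2 genes as high in such tumours. The rarity of such ratios therefore excludes nothing, although the plan had been to count it against noise. More fat tissue in the EiPS pool may account for part of Retn's difference and stays open: the lower of the differences of Adipoq and Fabp4 was 2.98, but that of Retn is only known to be at least 2.53, and the adipocyte list without Retn had a median of 0.73. Whether a uniform gain of intestinal tissue was the whole cause for Zg16 cannot be decided here. The other 19 intestine genes had a median of 1.01 (SD 1.13) and at most 2.80 (Tff3), against 4.72 for the lowest of Zg16's probe sets. But Zg16 was picked by the study and had the largest difference among genes above the floor on both arrays. Lower values in the other genes were therefore fixed beforehand. Expression of those genes in other tissues and a gain of goblet cells alone were not tested. A biological difference between the cell lines or between growing and regressing tumours stays open and was not tested.

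The lower skeletal muscle signals were set against 3 explanations. Scaling of the arrays alone is argued against by the list's median, which was at highest -1.23 under the 3 other scalings. Whether uniformly less muscle was the whole cause stays open. The SD of differences was 0.99 over all 21 measured members, 0.73 without Myh4 and 0.78 over the 9 dimmer members other than Myh4. It was 0.40 between probe sets, and 0.46, 0.46 and 0.47 in the median random list of matched expression. Such SDs were reached by 0.52%, 5.73% and 9.72% of random lists. Expression of some members in other cells, which would make their differences unequal, was not tested. Adult muscle of the host in the B6 ES pool cannot be told apart from a difference of the tumours' own muscle: 5 genes of early muscle had a median of -0.67, but they were chosen after their values were seen. A difference in the kind or maturity of muscle may also lie behind the pattern, and it was not tested.

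Meg3 and Rian, neighbouring noncoding RNAs of 1 imprinted cluster, were both higher in the EiPS pool. A fault of 1 probe set is argued against by the 5 probe sets of Meg3, the lowest of which differed by 2.54. More nuclear RNA in the EiPS sample stays open for Meg3: the median of 3 other nuclear-retained RNAs (Malat1 0.70, Neat1 1.49, Airn 1.74) less its lowest probe set came to -1.05, but 3 RNAs are too few, and Neat1 and Airn were chosen after their values were seen. For Rian it cannot be told apart from a change of the gene itself, because that median of 1.49 lies against 1.90 for Rian, at the edge of the spread between probe sets of 0.40, and how near counts as undecided was also set after the value was seen. A difference in imprinting between the ES and EiPS lines might give this pattern and was not tested.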
